A study of Homo sapiens with 6 samples.

How the data were processed

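The series measured total RNA from HaCaT keratinocytes by RNA sequencing in 3 libraries from cells transfected with an siRNA against PSENEN and 3 from cells transfected with a mismatch siRNA. Cells grew in high glucose medium with 10% serum, and 100 pmol of PSENEN siRNA was transfected with a lipid reagent, per the labels. Another group that received the transfection reagent alone is described in the labels but is not among the samples used here. The labels list Bowtie 0.12.2 and the mouse builds mm8 and mm9, which do not match the human files.

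Each deposited file is an assembly of 1 library by StringTie, which is named as the source of every line, and the values the authors deposited for each transcript are TPM, FPKM (both normalised within a library for length and depth) and coverage per base. The aligner used for these files, the StringTie version and its options, the strandedness of the libraries and the read length are not given in the sources used here. The build was checked against GENCODE 29 on GRCh38: of 92476 reference transcripts named in the files, 92263 were in that release and 90704 (98.3%) had the same position. The files name 29012 genes, of which 28815 were in GENCODE 29 and 28605 had a current symbol by ID. TPM sums over the transcripts of a library ranged from 886394 to 909066, below the sum that the unit gives for a complete library, and they were left as deposited.

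Gene values were sums of TPM over reference transcripts and over assembled transcripts that share an intron with a gene. The share of TPM assigned to genes in this way was 72.3% ± 0.507 in PSENEN siRNA libraries and 74.1% ± 0.753 in mismatch siRNA libraries, and the share from assembled transcripts that share an intron was 5.51% ± 0.195 and 6.38% ± 0.383. The files held 176034 ± 7103 and 189664 ± 4067 transcripts per library. In each of these 3 measures the groups did not overlap (SD, n = 3; exact permutation p = 0.1, the smallest possible). Unassigned single-exon transcripts took 12.0% ± 0.729 in PSENEN siRNA libraries and 11.1% ± 1.12 in mismatch siRNA libraries (SD, n = 3; exact permutation p = 0.3). The files used here give no counts, so depth was estimated from coverage divided by FPKM, at 9.16 to 15.6 gigabases per library, and no counting intervals are given.

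The comparison used limma 3.58.1 in R 4.3.3 with an intensity trend on log2(TPM + 1) over genes with at least 1 TPM in at least 3 libraries, with group as the only term and 4 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Of the 16424 genes tested, 11264 were protein-coding and 429 were listed at 0 in at least 1 library. Gene lists with at least 5 tested members (31 of 34) were tested with camera at its preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists, and members were also adjusted over the list alone. The contrast, the model, the lists, the alternatives listed first below and the rule for named genes were fixed before the data were examined. The rule names the γ-secretase subunits, up to 8 protein-coding genes with the largest rise and 8 with the largest fall among called genes whose groups do not overlap and whose higher mean is at least 5 TPM, and from each list up to 3 called members, or else its most abundant member. This gives 52 genes. Single values were compared by exact permutation tests, for which 3 against 3 libraries allow no p under 0.1.

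The steps were tested on simulated data with 200 changed genes: 71% of 2-fold and 94% of 4-fold changes were recovered, and 14 of 179 called genes were false. The changed genes were drawn from genes above a set mean level, so the rates of recovery do not cover genes at lower levels. Alternatives fixed in advance were other pseudocounts (0.1 and 5), no filter or a minimum of 5 TPM, FPKM, median-of-ratios scaling, quantile normalization, no trend, array weights, voom weights on coverage times length at 300 bases per fragment, the replicate number as a block, reference transcripts only, each library left out, an estimated correlation and fry. Added after the data were seen were assembled bases (coverage times length) scaled to the library total, only genes above 0 in all libraries, protein-coding genes only, and lists without genes that hold TGGTTCT in the 3′ UTR.

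The search for siRNA seed matches counted every 7-base word in the 3′ UTRs of tested protein-coding genes and compared genes with and without each word. Shared sequence was measured as the percentage of 31-base words of a gene's annotated transcripts that occur in another annotated gene, with 20% as the threshold. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for parsing, these searches and the figures.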

Results

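RNA sequencing measured transcripts in HaCaT cells, an immortalised human keratinocyte line, after transfection with an siRNA against PSENEN or with a mismatch siRNA as control. Each group held 3 libraries. PSENEN encodes a subunit of γ-secretase, the membrane protease that cleaves Notch receptors and other membrane proteins. The labels give 100 pmol of PSENEN siRNA and RNA extraction at 48 and 72 h, without saying which time the sequenced RNA came from. The deposited files hold transcript abundances and no read counts. The ratio of coverage to FPKM gives an estimate of 11.9, 11.3 and 9.16 gigabases of aligned sequence in PSENEN siRNA libraries 1 to 3 and of 15.6, 13.7 and 11.5 gigabases in mismatch siRNA libraries 1 to 3 (exact two-sided permutation p = 0.2; the smallest p that 3 against 3 libraries allow is 0.1). Spearman correlations of log2 levels across genes were 0.938 to 0.946 within groups and 0.929 to 0.936 between groups.

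The comparison asked what a lower PSENEN level did to the other γ-secretase subunits and to pathways of keratinocytes. PSENEN RNA was about 5-fold lower in cells with the PSENEN siRNA, and APH1A, NCSTN and PSEN2 did not change past the test. Few genes passed the test, and with all 6 libraries more of them were lower than higher. The lower genes included AXL, OLFM4, tissue factor (F3), urokinase (PLAU), TIMP2 and S100A9, and the higher genes included GCLC, SQSTM1 and TNFSF9. Of 45 lower genes with a 3′ UTR, 22 held TGGTTCT there, a sequence also found in PSENEN, against 13.6% of other genes. AXL and TIMP2 are among the 22, and 2 of 12 higher genes, SQSTM1 among them, held it too. The siRNA may have acted on such transcripts directly, so their falls cannot be assigned to lower PSENEN. Interferon-stimulated genes were lower as a group with the preset correlation of the list test (adjusted p = 0.261 with an estimated correlation), and Notch target genes as a group passed with neither. Unless stated otherwise, values below are gene levels in TPM as mean ± SD (n = 3 libraries per group), and changes are log2 differences of TPM + 1, PSENEN siRNA minus mismatch siRNA, which understate the fold change of genes at low levels.

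PSENEN (ENSG00000205155, GRCh38 chromosome 19, 35745114 to 35747519, plus strand) was at 1.75, 2.08 and 1.496 TPM in the PSENEN siRNA libraries and at 6.58, 12.6 and 7.47 TPM in the mismatch siRNA libraries. The means were 1.77 ± 0.294 and 8.87 ± 3.23, so that 20.01% of the control level was left (exact two-sided permutation p = 0.1). The change was -1.79 with a standard error of 0.25 and an adjusted p of 0.0470 over all genes, and of 0.00117 adjusted over the list alone. The call over all genes did not outlast the loss of any library: the adjusted p was 0.157, 0.138 and 0.154 without PSENEN siRNA library 1, 2 or 3, and 0.0889, 0.106 and 0.121 without mismatch siRNA library 1, 2 or 3, with changes between -1.53 and -1.96. Most of the signal was assigned to transcript ENST00000587708, at 1.38 ± 0.298 against 7.07 ± 1.57 TPM. The start of PSENEN overlaps the antisense gene U2AF1L4 (0.558 ± 0.300 against 1.40 ± 0.400 TPM, adjusted p = 0.312), and 50.1% of the 31-base words of its transcripts also occur in another annotated gene, so part of its level may belong to an overlapping gene. APH1A was at 79.0 ± 5.85 against 72.4 ± 3.26 TPM (change 0.12, adjusted p = 0.626). NCSTN was at 21.3 ± 4.40 against 23.8 ± 8.39 TPM (-0.12, adjusted p = 0.863) and PSEN2 at 2.53 ± 1.13 against 4.48 ± 1.28 TPM (-0.65, adjusted p = 0.358). APH1B, at 0.674 ± 0.590 against 0.742 ± 0.450 TPM, was below the level needed for testing.

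**Figure D1:**
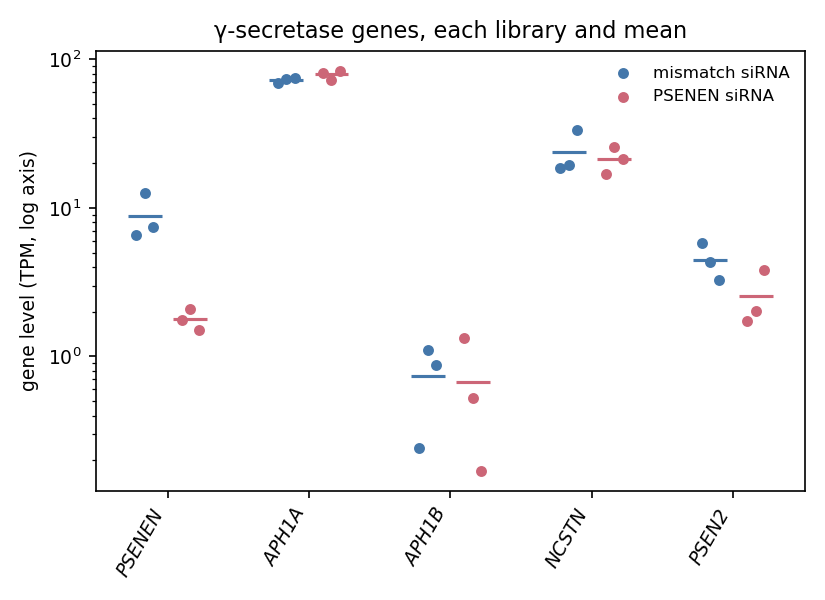
Levels of PSENEN, APH1A, APH1B, NCSTN and PSEN2 in TPM on a log axis, with a point for each library and a bar at the mean of the 3 libraries of a group. The PSENEN points lie between 1.496 and 2.08 TPM with the PSENEN siRNA and between 6.58 and 12.6 TPM with the mismatch siRNA, and the groups of the other genes shown overlap.

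Of 16424 genes tested, 84 passed an adjusted p of 0.05: 27 were higher and 57 lower in PSENEN siRNA cells. After quantile normalization 64 passed, 27 higher and 37 lower, so that the higher share was 42.2% in place of 32.1%. An unadjusted p under 0.05 was found for 2394 genes, where 821 would arise by chance. The groups did not overlap for any of the 84 genes, and for 22.3% of all tested genes, against 10% by chance. Among the 84 genes, 60 were protein-coding (14 higher, 46 lower) and 24 were of other types, among them 9 processed pseudogenes, 4 small nuclear RNAs and 4 microRNA genes. Without PSENEN siRNA library 1, 2 or 3 the count was 10, 9 and 12 genes, and without mismatch siRNA library 1, 2 or 3 it was 9, 12 and 10. Most of these were higher, not lower, without mismatch siRNA library 2 (8 higher, 4 lower) or 3 (8 higher, 2 lower). The filter of at least 1 TPM in at least 3 libraries also applied to these fits. A gene that reached 1 TPM only in the libraries of 1 group was not tested without a library of that group. HSPD1P11 (lower) and CSNK2A3 (higher) are examples, so the balance of directions could depend on which group lost a library. None of the 84 genes changed direction in those of these 6 fits in which it was tested, and CBX5, RNU2-2P and RPS15AP24, the last 2 named after their values were seen, passed in each of them. RNU2-2P and RPS15AP24 share 100% and 69.9% of the sequence words searched with another gene, so the source of their reads is uncertain. The p-values measure the spread between libraries, and whether these came from separate cultures is not given.

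The gene with the largest fall among named protein-coding genes was the histone gene HIST1H2BE (ENSG00000274290), at 14.3 ± 13.7 against 511 ± 24.5 TPM (change -5.43, adjusted p = 0.0266), with 33.8% of its 31-base words shared with another gene. The receptor tyrosine kinase gene AXL (ENSG00000167601) was at 1.44 ± 0.9 against 20.8 ± 6.70 TPM (-3.19, adjusted p = 0.0313) and OLFM4 (ENSG00000102837) at 6.10 ± 1.58 against 46.2 ± 13.5 TPM (-2.71, adjusted p = 0.0257). F3 (ENSG00000117525), which encodes tissue factor, was at 45.2 ± 13.0 against 243 ± 80.6 TPM (-2.39, adjusted p = 0.0380). CBX5 (ENSG00000094916), which encodes heterochromatin protein HP1α, was at 16.5 ± 1.29 against 60.2 ± 4.38 TPM (-1.81, adjusted p = 0.00334). The nucleotide receptor gene P2RY6 (change -1.93, adjusted p = 0.0266) and the cyclooxygenase gene PTGS1 (-1.59, adjusted p = 0.0473) were lower as well. The 3′ UTRs of AXL and CBX5, but also those of EIF4EBP2 and SQSTM1, which were higher, hold the 7-base word TGGTTCT, which also occurs in the coding sequence of PSENEN.

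The largest rise among named protein-coding genes was that of CSNK2A3 (ENSG00000254598), at 20.5 ± 1.85 against 0.642 ± 0.145 TPM (change 3.71, adjusted p = 3.77e-04), but 82.1% of its 31-base words are shared with another gene, so the source of its reads is uncertain. ARHGAP23 was at 345 ± 72.1 against 127 ± 25.1 TPM (1.43, adjusted p = 0.0448), a rise that was absent when the gene was measured in assembled bases scaled to the library total (-0.08), with voom weights (-0.07) or from reference transcripts alone (-0.00383). EIF4EBP2 (ENSG00000148730), which encodes a repressor of cap-dependent translation, was at 43.2 ± 0.251 against 18.7 ± 1.40 TPM (1.17, adjusted p = 0.0183). The glutathione synthesis gene GCLC (ENSG00000001084) was at 89.5 ± 6.26 against 45.3 ± 3.72 TPM (0.97, adjusted p = 0.0313) and TNFSF9 (ENSG00000125657), the gene for 4-1BB ligand, at 45.4 ± 1.14 against 22.7 ± 0.996 TPM (0.97, adjusted p = 0.0230). STEAP1 (1.11), SRM (1.04) and ATP5O (1.03) were also higher, and STEAP1 and ATP5O share 33.5% and 23.8% of their 31-base words with another gene. Of the 22 named genes that passed, PSENEN among them, CBX5 alone passed without each library in turn, and CSNK2A3 passed in the 3 of these fits in which it was tested. None of the 22 reversed in those of these fits in which it was tested.

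**Figure D2:**
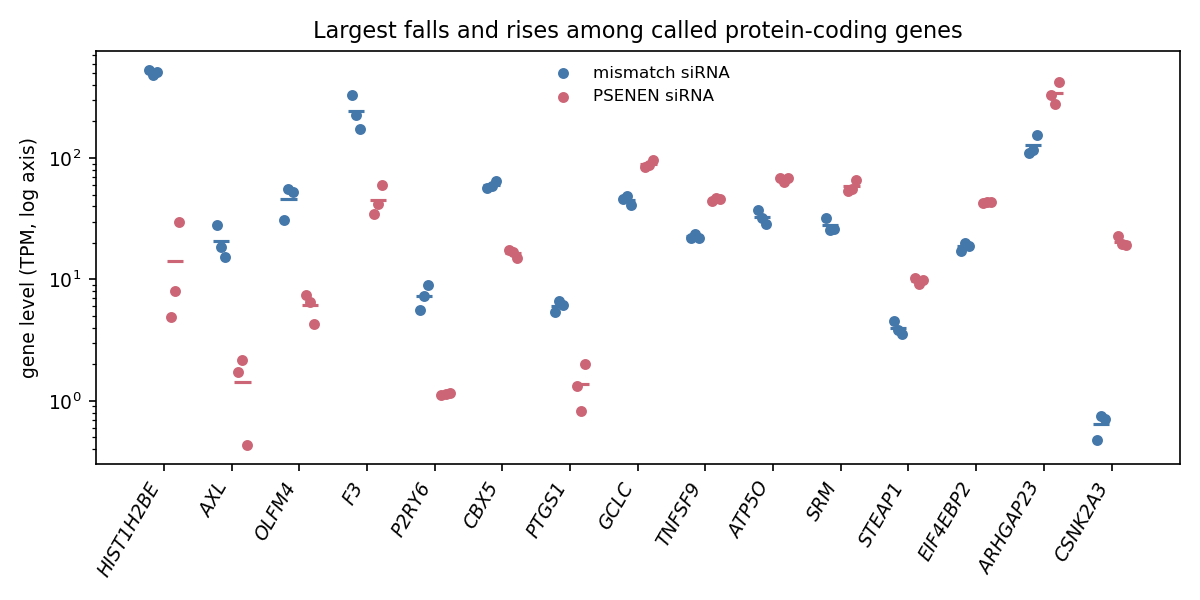
Levels in TPM on a log axis of the protein-coding genes with the largest falls and rises, with a point for each library and a bar at the mean of the 3 libraries of a group. The points of the groups do not overlap for any of these genes, and AXL lies between 0.430 and 2.16 TPM with the PSENEN siRNA and between 15.4 and 28.3 TPM with the mismatch siRNA.

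Interferon-stimulated genes were the list with the smallest p of the 31 tested. All 23 tested members had a negative change (median -0.58), IFI27 passed over all genes, and 13 were lower adjusted over the list alone. The camera adjusted p was 4.82e-08, and the adjusted p = 0.261 with an estimated correlation. IFI27 was at 0.0940 TPM in PSENEN siRNA library 1, was listed at 0 in libraries 2 and 3, and was at 1.74, 2.57 and 1.83 TPM in the mismatch siRNA libraries (adjusted p = 0.0448); a value of 0 may be a failed estimate. IFIT1 was at 5.47 against 11.8 TPM and IFI6 at 0.587 against 5.55 TPM, each lower adjusted over the list alone. Of the 10 lists that passed with the preset correlation, none passed with an estimated correlation. With fry, which tests whether the members of a list move, on balance, in 1 direction, 8 passed. The estimated correlation was below the preset 0.01 for basal keratinocyte genes (-0.0342), activation keratins (-0.0315) and metalloproteinases (-0.0385). A higher correlation between members is therefore not what removed these calls. In the other called lists it was above the preset, from 0.0204 (TGF-β) to 0.749 (mitochondrial transcripts). Whether the correlation removed the calls of those lists was not tested.

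Several epidermal lists were lower. The 7 antimicrobial and S100 genes all had a negative change (median -0.63, camera adjusted p = 0.00242, adjusted p = 0.435 with an estimated correlation, 0.108 with fry). S100A9 passed over all genes, at 185 ± 13.6 against 516 ± 95.6 TPM (change -1.46, adjusted p = 0.0282), and S100A8, S100A7 and LCN2 passed with it adjusted over the list alone. Of 15 basal keratinocyte genes, 12 were negative (median -0.29, camera adjusted p = 0.00356, adjusted p = 0.261 with an estimated correlation), none over all genes, and KRT14, LAMA3 and TP63 were lower adjusted over the list alone. That list did not pass with voom weights (0.0681), with reference transcripts only (0.0719) or in assembled bases scaled to the library total (0.0786). KRT14 was at 1473 ± 74.9 against 3563 ± 835 TPM (adjusted p = 0.0564), with an adjusted p of 0.0256 without mismatch siRNA library 1, but its change was 0.97 when only reference transcripts were counted. Among 12 activation and simple-epithelial keratins, 10 were negative (median -0.42, camera adjusted p = 0.00713, adjusted p = 0.261 with an estimated correlation), none over all genes, and KRT17, KRT4 and KRT6A adjusted over the list alone. Of 14 genes for matrix metalloproteinases and inhibitors, 10 were negative (median -0.28, camera adjusted p = 0.0109, adjusted p = 0.261 with an estimated correlation). TIMP2 was at 2.64 ± 0.145 against 9.26 ± 0.560 TPM (-1.50, adjusted p = 0.0187) and PLAU at 54.2 ± 4.15 against 126 ± 8.25 TPM (-1.20, adjusted p = 0.0177); PLAT and MMP10 joined them adjusted over the list alone. The list did not pass with voom weights (0.135) or in assembled bases (0.167). TIMP2 holds the word TGGTTCT in its 3′ UTR.

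Stress and signalling lists were lower as well. MAPK response genes had 16 of 18 members negative (median -0.28, camera adjusted p = 0.00472, adjusted p = 0.333 with an estimated correlation), none over all genes, and CCND1 and IER3 adjusted over the list alone. Unfolded protein response genes had 16 of 20 members negative (median -0.28, camera adjusted p = 0.00472, adjusted p = 0.346 with an estimated correlation), none over all genes; HSPA5, XBP1, PDIA4 and HSP90B1 were lower and DDIT4 higher adjusted over the list alone. The adjusted p was 0.0558 without PSENEN siRNA library 2 and 0.0508 with a minimum of 5 TPM. Inflammatory and NF-κB genes had 15 of 19 members negative (median -0.30, camera adjusted p = 0.0122, adjusted p = 0.333 with an estimated correlation), none over all genes, with IL1B, ICAM1 and CCL2 among 6 that were lower and CXCL1 higher adjusted over the list alone. That list had an adjusted p of 0.0966 with a minimum of 5 TPM, 0.0854 without mismatch siRNA library 2, 0.0607 without genes that hold TGGTTCT in the 3′ UTR and 0.0552 with only genes above 0 in all libraries. TGF-β response and matrix genes had 12 of 16 members negative (median -0.25, camera adjusted p = 0.0334, adjusted p = 0.333 with an estimated correlation), none over all genes, and TNC, FN1, TGFBR1 and CYR61 among those lower adjusted over the list alone. Its adjusted p was 0.187 with reference transcripts only, 0.125 without PSENEN siRNA library 3, 0.0932 with protein-coding genes only, 0.0719 with a minimum of 5 TPM, 0.0612 without mismatch siRNA library 1 and 0.0501 with array weights.

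The 13 mitochondrial transcripts, a list set as a check of RNA quality, were higher on average with the PSENEN siRNA, but not in every library. The mitochondrial share of TPM was 4.11%, 4.02% and 3.27% in PSENEN siRNA libraries 1 to 3. It was 3.49%, 3.44% and 3.25% in mismatch siRNA libraries 1 to 3 (exact permutation p = 0.3). PSENEN siRNA library 3 thus lay within the mismatch siRNA range, and the groups did not overlap for 4 of the 13 transcripts. All 13 transcripts had a positive change (median 0.16, camera adjusted p = 6.74e-04, adjusted p = 0.470 with an estimated correlation, 0.240 with fry), and none passed over all genes or adjusted over the list alone.

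**Figure D3:**
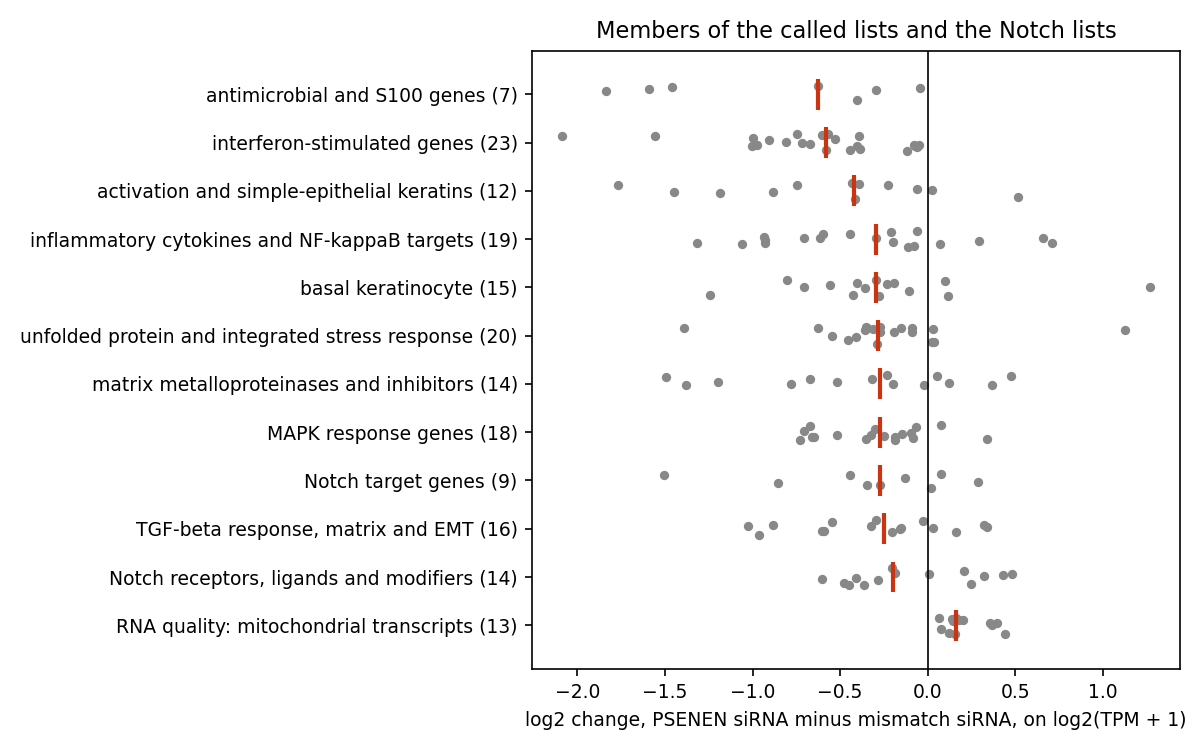
Log2 change of each tested member of the 10 lists that passed with the preset correlation and of the 2 Notch lists, with a point for each gene, a bar at the median of the list and the number of tested members in parentheses. All 23 interferon-stimulated genes lie below 0 and all 13 mitochondrial transcripts above 0, while the Notch receptors, ligands and modifiers lie on both sides.

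Notch genes did not pass as lists. Of 9 tested Notch target genes, 6 were negative (median -0.28, adjusted p = 0.107), none passed over all genes, and HES2 (8.84 against 16.8 TPM) and HES5 (1.15 against 5.09 TPM) were lower adjusted over the list alone. Without mismatch siRNA library 1 the list passed (adjusted p = 0.0108). HES1 was at 17.7 against 21.6 TPM and HEY1 at 4.68 against 4.59 TPM. The 14 Notch receptors, ligands and modifiers had 8 negative members (median -0.20, adjusted p = 0.803) and none passed either way; JAG1 was at 43.4 against 60.6 TPM and NOTCH3 at 11.1 against 15.7 TPM. Among 14 other γ-secretase partners and substrates (adjusted p = 0.125) only EFNB1 passed, lower adjusted over the list alone. With no filter on low values this list passed (adjusted p = 0.0496). The γ-secretase subunits had a list adjusted p of 0.235 and the 5 tested neighbours of PSENEN on chromosome 19 of 0.534, with KMT2B at 7.36 against 6.49 TPM.

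Differentiation and junction lists did not pass: spinous genes had an adjusted p of 0.145, with DMKN lower adjusted over the list alone, and cornified envelope genes 0.0952, with TGM1 lower (4.27 against 10.3 TPM) and FLG higher (12.8 against 5.19 TPM) adjusted over the list alone. In the desmosome and tight junction list (0.313), CLDN1 was higher (119 against 79.2 TPM) and OCLN lower (9.78 against 21.5 TPM) adjusted over the list alone. Without mismatch siRNA library 1 the spinous (0.0171), cornified envelope (0.0118) and junction (0.0369) lists passed, and without PSENEN siRNA library 1 the cornified envelope list passed (0.0343). With all libraries, the cornified envelope list passed with reference transcripts only (0.00424) and the spinous list with no filter on low values (0.00307). S phase genes (median 0.07, adjusted p = 0.0753) passed in 9 of 24 alternatives, among them the fits without PSENEN siRNA library 1 (0.0445) or 2 (0.0464) and without mismatch siRNA library 1 (0.0118), while G2 and M phase genes had an adjusted p of 0.991 (TOP2A 133 against 129 TPM). For p53 target genes it was 0.991, with CCNG1 higher and CDKN1A lower adjusted over the list alone. Apoptosis regulators had an adjusted p of 0.241 with camera and 0.0158 with fry, with CFLAR, BID and BAK1 lower and BMF higher adjusted over the list alone.

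The adjusted p was 0.783 for EGFR family genes, 0.783 for PI3K, AKT and mTOR components and 0.416 for Wnt genes, where DKK1 was higher and WNT4 lower adjusted over the list alone. In the cholesterol list (0.0952) CYP51A1 passed over all genes, at 27.1 ± 0.187 against 48.0 ± 3.54 TPM (adjusted p = 0.0395, with 83.0% of its 31-base words shared and TGGTTCT in its 3′ UTR), and SQLE and MVD passed with it adjusted over the list alone. That list passed without PSENEN siRNA library 1 (0.0343) or mismatch siRNA library 1 (0.0242), and with no filter on low values (0.0465). In the NRF2 list (0.783) GCLC passed over all genes, and adjusted over the list alone AKR1C1 and AKR1C2 were higher, GCLM and NQO1 lower. In the lysosome and autophagy list (0.255) SQSTM1 passed over all genes, at 608 ± 60.9 against 318 ± 31.4 TPM (0.93, adjusted p = 0.0395, 23.6% of words shared), and adjusted over the list alone CTSA was higher and BECN1 and CTSB were lower. Hypoxia genes had an adjusted p of 0.368 (0.0343 without mismatch siRNA library 1), RNA interference genes 0.931 and replication-dependent histones 0.378, and none of their members passed either way. The medians of the G2 and M phase, p53, NRF2, lysosome and chromosome 19 neighbour lists changed sign under other scalings, and the G2 and M phase, NRF2 and lysosome lists had a negative median with a test direction of up. Of marker lists for other cell types, 1 fibroblast gene (COL1A1, 1.27 against 2.40 TPM), 3 leukocyte and endothelial genes (CD68, CD14 and VWF) and 0 melanocyte genes were at a level that could be tested, too few for a list test, and none of the 4 genes passed.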

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

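Measures in assembled bases scaled to the library total, only genes above 0, protein-coding genes only and lists without TGGTTCT genes were alternatives chosen after seeing the data. The count of 84 called genes (27 higher, 57 lower) was 133 with array weights (97 lower), 152 in assembled bases (53 higher, 99 lower, 59 shared with the 84) and 6 with the replicate block (3 higher, 3 lower), a term that uses degrees of freedom; same-number libraries did not pair, with correlations of -0.0540, 0.00143 and -0.0170. Lower genes numbered 90 with a minimum of 5 TPM and 37 after quantile normalization. Without 1 library at a time, 9 to 12 genes were called (1 to 8 higher, 2 to 11 lower). These fits had fewer samples and, with the filter unchanged, fewer genes tested (15883 to 15972 in place of 16424). Neither was tested as a cause. The PSENEN change of -1.79 missed the threshold at -1.01 (pseudocount 5, adjusted p = 0.0602), -1.79 (no filter, 0.0889, with more genes tested; no trend, 0.0547; replicate block, 0.228), -1.28 (FPKM, 0.0574), -1.73 (median-of-ratios, 0.0544), -1.74 (quantile, 0.0518), -2.21 (voom weights, 0.0586) and -1.53 to -1.96 without 1 library; over its 21 alternatives the adjusted p ranged from 0.0389 to 0.228, and 7 kept the call. Of 31 lists, 10 were called, 0 with an estimated correlation and 9 to 16 without 1 library. Over the 734 list results, 683 were the same, 29 lost a call and 22 gained one. ARHGAP23 reversed to -0.0676 with voom weights, -0.00383 with reference transcripts only and -0.0773 in assembled bases. Over 1058 results of 51 other named genes, 891 were the same, 160 lost a call and 4 gained one; 10 of the 30 not called changed sign in 22 results. Where no cause is named, the cause was not tested. The alternatives meant for count files were not run, because counts were not used here, and without counts the depth behind a single gene's value is unknown.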

Other observations

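The gene groups of the first paragraph, the word search over all genes, and the tests on base composition, on switching values, on shared sequence and on interferon-stimulated genes were chosen after the results were seen. Genes of the plasminogen and coagulation systems were lower together in PSENEN siRNA cells: all 12 tested members were negative, with a median change of -0.74 (camera p = 4.29e-10, adjusted over 6 such groups 2.58e-09, adjusted p = 0.0427 and unadjusted p = 0.0209 with an estimated correlation). The 6 groups were put together after the results were seen, so none of their p-values is independent support. Adjustment was over these 6 groups alone, so an adjusted p of 0.0427 cannot be set against those of the lists fixed in advance. F3, PLAU and THBD passed over all genes, THBD at 8.03 ± 1.01 against 18.1 ± 2.01 TPM. The other 9 members gave a limma camera p of 4.94e-06 at the preset correlation. They include PLAT, already seen to be lower, so this p is no independent support. PLAT was at 8.38 ± 2.23 against 23.1 ± 3.89 TPM, F2R at 5.08 ± 0.883 against 8.96 ± 0.396 TPM and SERPINB2 at 20.7 ± 4.06 against 51.2 ± 21.2 TPM. The 13 tested serpins, of which 3 are in that group as well, were all negative (median -0.60, adjusted p = 1.75e-05, adjusted p = 0.0427 with an estimated correlation), and none passed over all genes; SERPINB7 was at 25.4 ± 0.599 against 39.9 ± 1.75 TPM. Counted in assembled bases scaled to the library total or with voom weights, 11 of the 12 and 11 of the 13 were negative, and counted in FPKM 1 serpin was not tested. Among 15 S100 genes, 13 were negative (median -0.48, adjusted p = 3.83e-05, adjusted p = 0.122 with an estimated correlation), but 9 were negative in FPKM and 10 in assembled bases, the median was -0.28 without mismatch siRNA library 2, and S100A2 was at 266 ± 8.43 against 111 ± 109 TPM. Cytosolic ribosomal protein genes were slightly higher (52 of 78 positive, median 0.09, adjusted p = 8.44e-04, adjusted p = 0.0427 with an estimated correlation). Their median was 0.0541 without PSENEN siRNA library 3 and 0.175 with voom weights. HLA genes had an adjusted p of 0.0161 (0.298 with an estimated correlation; p = 0.0698 without mismatch siRNA library 3, unadjusted), and 3 tested genes for TYRO3, AXL and their ligands 0.0513 (p = 0.0337 without PSENEN siRNA library 2, unadjusted).

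Genes lower in PSENEN siRNA cells carried a sequence of the PSENEN transcript in their 3′ UTRs more often than other genes. Of 45 lower genes with a 3′ UTR, 22 held TGGTTCT (48.9%), against 1448 of 10626 other genes (13.6%), with a Bonferroni adjusted p of 2.82e-05 over the 1668 words of PSENEN. Of 12 higher genes with a 3′ UTR, 2 held it (EIF4EBP2 and SQSTM1). Over the 10671 tested protein-coding genes with a 3′ UTR of at least 50 bases, this word had the lowest z (-11.7) of 16362 words. Of 94 other orders of the same bases, chosen to share no long run of bases with it, none went below -2.95. This argues against base composition. Orders left out for sharing such a run went lower (GGTTCTT -6.00, TTGGTTC -4.92, TCTGGTT -4.54). TGGTTCT was also the lowest word in each of the 9 pairs of a PSENEN siRNA and a mismatch siRNA library, and in none of the 6 pairs within groups. The 9 pairs reuse the 6 libraries in which the word was found, so they are no separate support. Of the 16362 words searched, 1668 occur in PSENEN. A candidate explanation is that the PSENEN siRNA acted through its seed on other transcripts, among them AXL, CBX5, TIMP2, SDC4, GJA1 and CPT1A; the siRNA sequence was not used here, a small RNA of the cell with the same seed stays open, and lower PSENEN as the cause of changes in genes without the word was not tested.

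The 1470 genes with the word had a median change of -0.17 and the 9201 without it of -0.06. Among the carriers, the 257 in which an A follows the word had -0.26 (95% interval -0.30 to -0.18) and the 1213 others -0.16 (-0.18 to -0.14); the intervals overlap, and the difference was not tested. The 1071 genes with the word only in the coding sequence had a median of -0.08. No word stood out on the other side, where the highest z was 4.22 (Bonferroni adjusted p = 0.403). Of the 10 list calls, 9 stayed without the genes that hold the word, and the inflammatory and NF-κB list, at an adjusted p of 0.0607, did not.

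Some genes not annotated as protein-coding changed by at least 2 on the log2(TPM + 1) scale: RNU2-2P was at 14.4 ± 1.02 against 693 ± 67.6 TPM and HSPD1P11 at 0.215 ± 0.0381 against 17.9 ± 0.834 TPM, while RNU1-3 was at 227, 1765 and 232 TPM with the PSENEN siRNA and at 6.82 ± 0.571 TPM with the mismatch siRNA. There were 8 such calls, and another split of the 6 libraries, PSENEN siRNA 1 and 2 with mismatch siRNA 2 against the rest, gave 8 as well, while the remaining 8 splits gave 0 to 4. Such values may therefore switch in part between libraries whatever their group. RNU2-2P and RPS15AP24, which are among the 8 genes, nevertheless passed without each library in turn. However, RNU2-2P and RPS15AP24 share 100% and 69.9% of their words with another gene, so the source of their reads is uncertain. RNU1-3 shares 100% and HSPD1P11 2.03%. Reads shared between near-identical copies cannot be told apart from other sources, since 3 of the 8 and 2298 of 5100 other tested genes of these types shared 20% or more of their words (Fisher's exact test, two-sided p = 0.737), and reads were not analysed here.

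Interferon-stimulated genes had mean log2 levels of 2.62, 2.66 and 2.84 in PSENEN siRNA libraries against 3.53, 3.27 and 3.25, a list call that was lost at an adjusted p = 0.261 with an estimated correlation. The 22 of 23 members without TGGTTCT had a median change of -0.575, which argues against matches to the whole word in their own 3′ UTRs. Shorter matches were not searched in these genes, although a word that shares GGTTCT was also low over all genes searched (AGGTTCT, z = -5.54). None of 10000 random lists of genes at the same levels had a median as low as that of the list, -0.58 (lowest -0.437), which argues against low depth. A response to the mismatch siRNA may instead have raised these genes in the control cells, which cannot be told apart from a fall with less PSENEN, because 0 of the groups used here lacked an siRNA. Lower PSENEN stays among the open explanations, untested.

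Only 10 splits of the 6 libraries into 3 and 3 exist, too few for a share under 0.05: the real split gave 84 genes and the highest of the others 10.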
